A study of Paralichthys olivaceus with 24 samples.

How the data were processed

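RNA was sequenced from tissues of olive flounder (Paralichthys olivaceus) held at 12, 18, 23 or 28 °C. The labels describe 24 samples from 3 tissues (gill, liver and muscle) and 2 series, named A and C in the sample titles, with 1 sample for each tissue, series and temperature. Per the labels' protocols, 120 fish aged 9 months were kept at 12 °C and divided into 8 treatment groups of 15 fish, and an acute and a chronic heating regime were used. In the acute regime the temperature was raised in steps at 3 h intervals, and in the chronic regime it was raised at 3 °C per h and then held for at least 20 h. No label spells out that A and C stand for these regimes, so the series are called A and C here. The table used here has columns for 4 of the 24 samples, the muscle samples of series C at 12, 18, 23 and 28 °C. The other 20 samples, which include all gill and liver samples and the whole of series A, were not analysed here. The labels speak of duplicates, but each temperature has 1 column, and whether a column is a pool or a mean of duplicates is not stated. Each column is called a library here, and no value below has a replicate.

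The deposited table gives 1 row per gene with an RPKM value (reads scaled by transcript length and by the mapped reads of the library) for each of the 4 samples, per the file headers. TopHat2 and Cufflinks are named in the submitters' processing notes, without versions. The genome build and the annotation are not given in the sources used here. RPKM values of genes with near-identical copies, such as the heat shock protein 70, heat shock protein 90 and skeletal actin genes, are uncertain, because the way reads were shared between copies is not stated. The table has 11646 rows with values, of which 4120 are named by a gene symbol and 7526 by a numbered gene ID. Of the numbered IDs, 5836 were found in a RefSeq gene table of the assembly ASM2471397v2, which was used for names alone, and 2788 took a symbol from it. The remaining 4738 rows have no symbol, and no row without a symbol was chosen by a naming rule.

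The deposited table also holds the authors' comparison of each warmer library with the 12 °C library and the authors' cluster number for each gene (7 clusters). The 3 comparison columns were made by the authors as natural log values, as read from the deposited values, although per the file headers they are log2 values. In 11635, 11641 and 11633 rows for 18, 23 and 28 °C they equal the natural log of the RPKM ratio plus a constant, within 0.00001. RPKM values below 0.01 were set to 0.01 in these ratios. The constants correspond to factors of 0.942, 1.272 and 0.91. The remaining 11, 5 and 13 rows lie at a lower limit of 0.01 as a ratio. All 11646 rows have an authors' value of at least the natural log of 2 in size in 1 or more of the 3 comparisons. The table is thus a selection of genes at least 2-fold apart from the 12 °C library, and genes without such a difference are not in it. Shares of the table are therefore not shares of the transcriptome, and random gene lists drawn from it hold only such genes.

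The table holds no counts, so the absolute depth is unknown. Values of many genes with few reads lie on steps that are whole multiples of what 1 read is worth. Comparing these steps between libraries gave depths of 1.004, 0.981 and 1.013 at 18, 23 and 28 °C relative to the 12 °C library. For 2309 of the 9723 rows with 3 or 4 values above 0 (23.7%), all values could be read as whole reads within 0.01 reads. Among such rows with a mean under 0.1 RPKM this held for 1453 of 1928 (75.4%), and the rest could not be read. After each value had been moved by up to 3% at random, 0.3% could be read in this way. These are the smallest whole-read readings, and their median was 14 reads summed over the 4 libraries. Where the authors' 2-fold calls fell on such rows, the reads of the pair of libraries were compared with an exact binomial test (two-sided), which compares these libraries and not the temperatures.

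Folds were computed as log2((RPKM + 1)/(RPKM at 12 °C + 1)), which understates the change of low genes. A gene was counted as higher or lower when this fold was at least 2 in either direction and the mean RPKM of the pair was at least 1. These counts carry no p-value, because each temperature is 1 library. Gene lists were described by their median log2 fold and its percentile among 10000 random lists of the same size, drawn from 20 bins of mean expression. Many lists are held only in part. Extracellular matrix has 7 rows and the contractile list 27, against 25 and 62 matches among the RefSeq genes used for names. For glycolysis the numbers are 16 and 28. List values therefore describe the selected members and not whole pathways. A temperature slope was fitted with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with temperature as a number, moderated variances with a trend, and Benjamini-Hochberg adjustment at 0.05 (two-sided). Genes with at least 1 RPKM in at least 2 libraries were fitted, which leaves 2 residual degrees of freedom over the 4 libraries. The scatter about the line then includes any curvature of the response. Gene lists with at least 5 fitted members were tested on the slope with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.

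Lists, thresholds and the rule for named genes were set before the data were examined. The design assumed 24 libraries. The slope was therefore fitted without a term for series, and the planned tests in gill and liver, between the series and between tissues were not run. For folds, the rule named the 5 genes with the largest change in each direction at 28 °C among named genes with a mean RPKM of at least 5. For the slope, where no gene passes, it named the 10 genes of each direction with the smallest unadjusted p, as values and not as calls, among genes with a symbol, a maximum of at least 5 RPKM over the libraries and a difference between 28 and 12 °C with the sign of the slope. The genes named at 18 and 23 °C follow the fold rule, but its use there was decided after the values were seen. Members of gene lists other than the heat shock list were chosen after the values were seen and by no fixed rule, so that members with larger folds, such as pfkfb3 of the hypoxia list, atf3 of the immediate early list and prss1 of the pancreas list, were in some cases not named. List members were matched by symbol, and a few matches do not belong by function. The egg list took zpr1, which encodes a zinc finger protein, and the xenobiotic list took cyp27a3 and cyp20a1.

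Alternatives set before the data were examined were a pseudocount of 0.1, no filter on low values, scaling of each library by its median log2 ratio to the mean library, leaving out each library in turn, and the estimated correlation. Chosen after seeing the data were scaling by the authors' constants and counting without the liver, exocrine pancreas and acute phase lists. The slope fit was tested on simulated data of the 4075 genes with a set of changed genes. It recovered 19.1% of the 68 genes given a log2 change of 1 from 12 to 28 °C. It recovered 89.4% of the 66 genes with a change of 2 and all 66 with a change of 4. There were 6 false calls, and the residual SD was 0.346. Every simulated gene had this same SD and all changes were straight lines. The shares recovered are therefore not the power for real genes, whose scatter differs and whose responses can curve.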

Results

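Muscle of olive flounder, a flatfish farmed in East Asia, was compared at 4 water temperatures to describe how its gene expression differs as the water warms. Each of the 4 libraries came from series C, with 1 library at 12, 18, 23 and 28 °C, and the 12 °C library served as the reference for the others. The values are the authors' RPKM for 11646 genes that the authors' table had selected as at least 2-fold apart from 12 °C in 1 or more comparisons. Relative depths were close, at 1.004, 0.981 and 1.013 times that of the 12 °C library. Each temperature has 1 column of values, called a library here, and whether a column combines duplicates is not stated. No temperature had a replicate column, so the folds below describe these libraries and have no error estimate.

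Among genes with a symbol, the 5 with the largest positive folds at 28 °C were chaperone genes or their partners. The inducible heat shock protein 70 gene hspa1b was at 1.68 RPKM at 12 °C and 5326 RPKM at 28 °C, a log2 fold of 10.96. The cytosolic chaperone hsp90aa1.1 went from 21.1 to 4188 RPKM (log2 fold 7.57), and hspbp1, an exchange factor of the same hsp70 system, from 1.78 to 464.3 RPKM (7.39). The small heat shock protein genes hspb9l and hspb1 were at 5.07 and 44.2 RPKM at 12 °C and at 691.8 and 3999 RPKM at 28 °C (6.83 and 6.47). Of the 29 heat shock genes that met the expression minimum, 26 were at least 2-fold higher at 28 °C and 0 were at least 2-fold lower. The exception in direction was hspb6, a small heat shock protein of muscle, at 367.9 RPKM at 12 °C and 193.5 RPKM at 28 °C. The median log2 fold of the 31 listed genes was 3.44, above all 10000 random lists. At 18 and 23 °C the median of this list was 0.17 and 0.29, at the 99.13 and 99.99 percentiles, with 3 and 6 members at least 2-fold higher. Genes for myosin-folding factors, which are in the list of contractile genes, shared this profile: smyd1 was at 36.7 and 2429 RPKM at 12 and 28 °C, and unc45b at 25.6 and 888 RPKM.

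**Figure D1:**
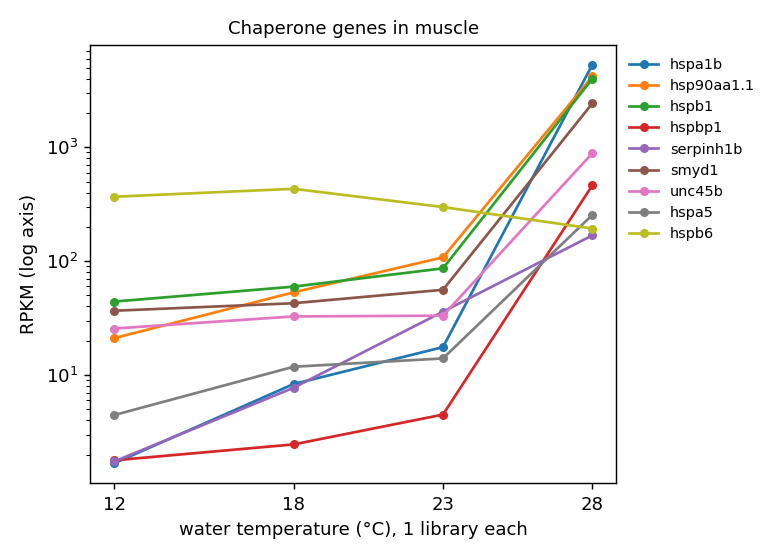
RPKM (log axis) of 9 chaperone genes against water temperature (°C), with 1 library per point and lines joining the points of a gene. From 23 to 28 °C hspa1b goes from 17.6 to 5326 RPKM, while hspb6 is lower at 28 °C (193.5 RPKM) than at 12 °C (367.9 RPKM).

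Genes of the endoplasmic reticulum stress response were also higher at 28 °C. Of 24 members that met the minimum, 22 were at least 2-fold higher and 0 lower, with a list median of 1.86 on the log2 scale, above all 10000 random lists. The lumenal chaperone hspa5 was at 4.45 RPKM at 12 °C and 255.0 RPKM at 28 °C, and the disulfide isomerases pdia6 and pdia4 were at 4.46 and 3.35 RPKM at 12 °C and at 57.8 and 36.5 RPKM at 28 °C. Immediate early genes, transcription factors induced within minutes of many stimuli, had 20 of 21 members at least 2-fold higher, with a median of 2.11, again above all random lists. Among them egr1 was at 4.24 and 68.03 RPKM, junbb at 2.59 and 47.8 RPKM, and fosl1 at 0.055 and 32.2 RPKM at 12 and 28 °C.

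Lists of metabolism and cell fate had smaller folds at 28 °C. Of 11 glycolysis members, 10 were at least 2-fold higher, with a list median of 1.19 at the 99.93 percentile. They included aldoc at 6.09 and 46.8 RPKM, hk1 at 1.63 and 13.9 RPKM and gapdhs at 20.4 and 102.1 RPKM at 12 and 28 °C. Of 15 hypoxia genes, 10 were at least 2-fold higher (median 1.39, percentile 99.66). The collagen prolyl hydroxylase subunits p4ha2 and p4ha1 were at 1.82 and 2.69 RPKM at 12 °C and at 83.3 and 40.98 RPKM at 28 °C, and the glucose transporter slc2a1b was at 6.65 and 73.8 RPKM. Of 11 apoptosis and p53 genes, 8 were at least 2-fold higher and 1 was lower (median 1.34, percentile 97.94). The caspase gene casp8 was at 2.08 and 34.6 RPKM and gadd45g, a growth arrest gene, at 4.67 and 45.0 RPKM, while sesn1, a sestrin that restrains growth signalling, was at 52.8 and 6.62 RPKM. The medians of the antioxidant and oxidative phosphorylation lists, 1.12 and 0.79, lay at the 94.0 and 85.56 percentiles. These lists have 9 and 8 rows here, against 33 and 90 matches among the RefSeq genes, so the medians describe selected members alone. The desaturase gene scd was at 6.26 and 197.3 RPKM, although the median of the 14 fatty acid synthesis genes was 0.01. The xenobiotic list had 0 members higher and 1 lower at 28 °C, and the egg yolk and egg coat list 1 higher and 0 lower, the higher gene being zpr1.

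**Figure D2:**
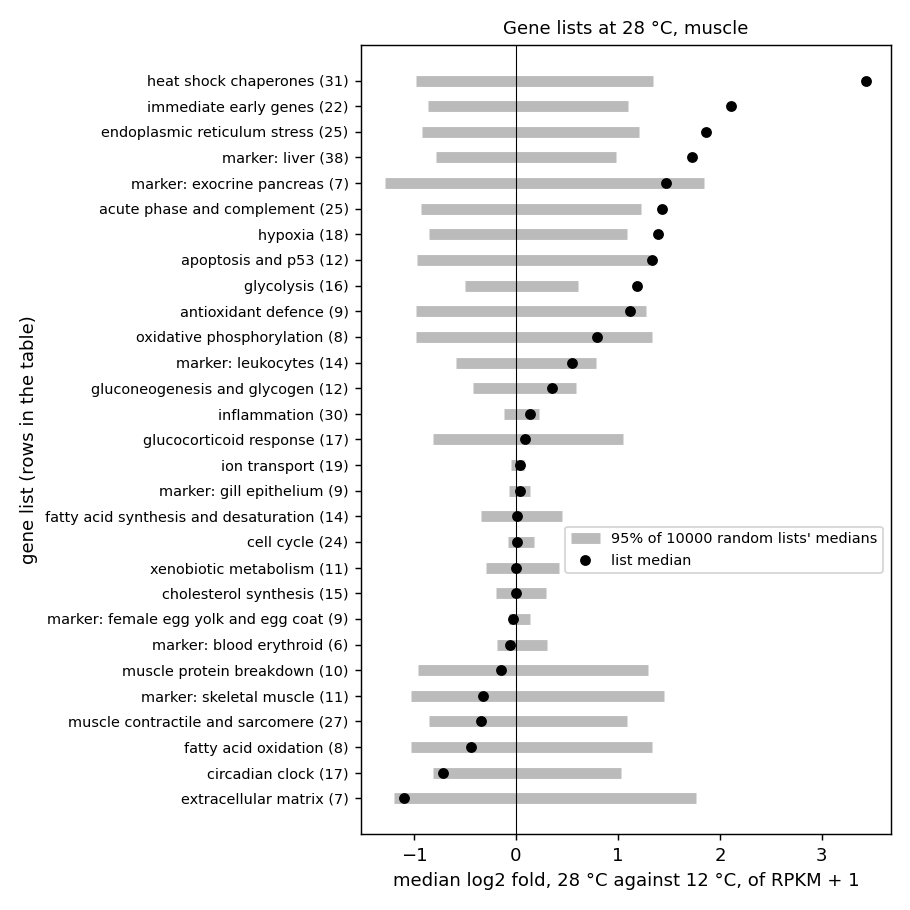
Median log2 fold of RPKM + 1 at 28 °C against 12 °C (horizontal axis) for each gene list with at least 5 rows (vertical axis, rows in brackets), with 1 library per temperature. Black points are list medians and grey bars span 95% of the medians of 10000 random lists matched on expression; the heat shock list lies at 3.44, outside its bar.

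Among genes with a symbol and a mean of at least 5 RPKM over the pair, the 5 with the largest negative folds at 28 °C were sbk3, clk2b, cxcl13, pik3r1 and slc7a8a. The SH3-binding kinase gene sbk3 was at 36.8 RPKM at 12 °C and 0.623 RPKM at 28 °C (log2 fold -4.54), and the splicing-factor kinase gene clk2b at 16.5 and 0.412 RPKM (-3.63). The chemokine gene cxcl13 was at 28.2 and 1.69 RPKM (-3.44). A regulatory subunit of phosphoinositide 3-kinase, pik3r1, was at 43.2 and 3.39 RPKM (-3.33), and the amino acid transporter gene slc7a8a at 31.4 and 2.25 RPKM (-3.31). Of 14 circadian clock genes, 7 were at least 2-fold lower and 0 higher, but the list median of -0.72 lay at the 6.58 percentile, inside the range of random lists. Its members rorca, ciart and per1b were at 6.96, 18.1 and 6.66 RPKM at 12 °C and at 0.533, 2.69 and 1.24 RPKM at 28 °C. Of 6 extracellular matrix genes, 4 were lower and 1 was higher (median -1.10, percentile 4.35), with postnb at 57.4 and 12.6 RPKM. Contractile genes as a list had a median of -0.34 at the 20.45 percentile but a mean of 0.07, since smyd1 and unc45b are members, and the calcium-binding parvalbumin gene pvalb1 was at 6441 and 2336 RPKM. The cold-inducible RNA-binding protein gene cirbp was at 226.4, 188.6, 110.8 and 91.2 RPKM from 12 to 28 °C.

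Over all genes, 1497 were at least 2-fold higher and 984 at least 2-fold lower at 28 °C among 4378 that met the minimum. The corresponding numbers were 314 and 110 of 4097 at 18 °C, and 113 and 408 of 3793 at 23 °C. The split between directions depended on the scaling of the libraries. Each library's median log2 ratio to the mean library was set against that of the 12 °C library. It differed by -0.112, -0.33 and -0.263 at 18, 23 and 28 °C. Scaling by median ratios removes this shift by taking that median as equal in all libraries. That assumption is not secured here, because the table holds only genes selected as at least 2-fold apart from 12 °C in some comparison. At 28 °C, 56.7% of the genes that met the minimum were at least 2-fold apart. Whether the shift is a library offset or the balance of genes that differ was not tested. The share of higher genes at 28 °C was 60.3% as deposited, 75.3% after median scaling and 53.4% with the authors' constants. At 23 °C the share of higher genes was 21.7% as deposited, 62.6% after median scaling and 52.4% with the authors' constants, so the larger direction at 23 °C turned with the scaling. At 18 °C these shares were 74.1%, 82.5% and 67.9%, and 61.5% with a pseudocount of 0.1. Among the 3634 genes that met the minimum in both pairs, 984 were lower at 28 °C and 407 at 23 °C, and 264 were lower at both. Independent lists of these sizes would share 110.2, and unchanged libraries set against the same 12 °C library would share 12.9 in a simulation. Among the same genes 1077 were higher at 28 °C and 107 at 23 °C, and the shared number was 74, against 31.7 for independent lists and 13.3 for unchanged libraries. These overlaps depended on the scaling: the shared lower genes numbered 99 after median scaling and 141 with the authors' constants (24.6 and 63.7 for independent lists), and the shared higher genes 167 and 136 (82.0 and 55.1). The simulation gave every gene the same noise, with an SD of 0.346 on the log2 scale, and was not matched to the numbers of genes called. Its values of 12.9 and 13.3 therefore do not measure what the shared 12 °C library adds to lists of these sizes. Part of the excess may come from the shared 12 °C library.

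**Figure D3:**
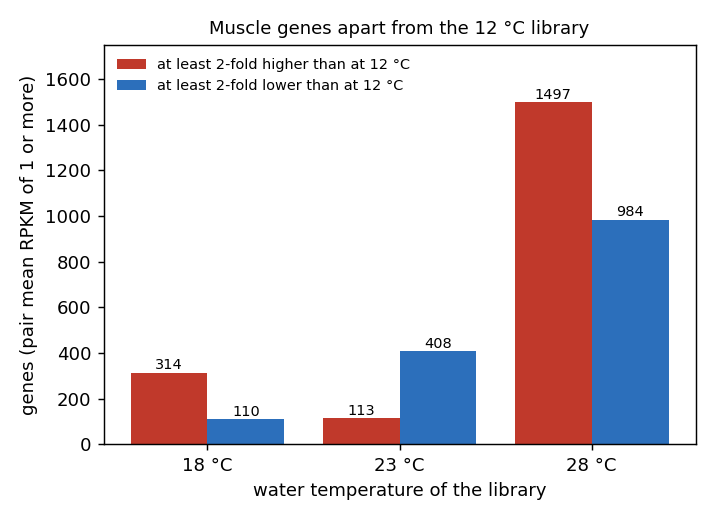
Number of genes (vertical axis) at least 2-fold higher (red) or lower (blue) than in the 12 °C library, for the libraries at 18, 23 and 28 °C (horizontal axis), among genes with a pair mean of at least 1 RPKM and with 1 library per temperature. The numbers higher are 314, 113 and 1497 and the numbers lower 110, 408 and 984, as deposited; at 23 °C the larger direction changes with the scaling.

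At 18 °C the genes with a symbol furthest above 12 °C were those of plasma proteins made in liver. The apolipoprotein gene apoa4 was at 14 RPKM at 12 °C, 1544 RPKM at 18 °C, 18.3 RPKM at 23 °C and 133.6 RPKM at 28 °C. The apolipoprotein gene apoa2, the fetuin gene ahsg1, the hemopexin gene hpxa and the transferrin gene tfa were at 9.67, 3.70, 0.817 and 4.92 RPKM at 12 °C and at 991.3, 395.2, 145.2 and 395.9 RPKM at 18 °C. Of 34 liver markers that met the minimum, 33 were at least 2-fold higher at 18 °C and 0 lower. Only 14 of the 38 listed markers were at 1 RPKM or more at 12 °C. Most of the 34 thus met the minimum through their 18 °C values, which favours a call as higher. The list median, which takes all 38 markers without the minimum, was 4.67 on the log2 scale, above all 10000 random lists. The median was 0.02 at 23 °C and 1.73 at 28 °C. Of 6 exocrine pancreas markers, all 6 were at least 2-fold higher at 18 °C (median 3.55, percentile 99.99), with the carboxypeptidase gene cpb1 at 3.42, 54.9, 5.10 and 14.8 RPKM from 12 to 28 °C. The acute phase and complement list, which shares 9 members with the liver list, had 19 of 23 members higher and 2 lower at 18 °C (median 3.47). Without these 3 lists, 265 genes were higher and 108 lower at 18 °C. Of these 265 higher genes, 153 lay within 2-fold of 12 °C at 23 °C and had an excess over 12 °C at 28 °C between 0.5 and 2 times the liver list's median share. Of all 314 higher genes at 18 °C, 192 (61.1%) followed this pattern. Others did not, such as hspa1b (8.33, 17.6 and 5326 RPKM at 18, 23 and 28 °C) and acta1a (395.5, 417.1 and 308.9 RPKM). Higher members of the gluconeogenesis list at 18 °C included fbp1b (0.126 and 4.91 RPKM at 12 and 18 °C) and pck2 (0.141 and 4.05 RPKM), and of the fatty acid list thrsp (0.54 and 73.7 RPKM). At 28 °C, 1463 genes were higher and 981 lower without the 3 lists.

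**Figure D4:**
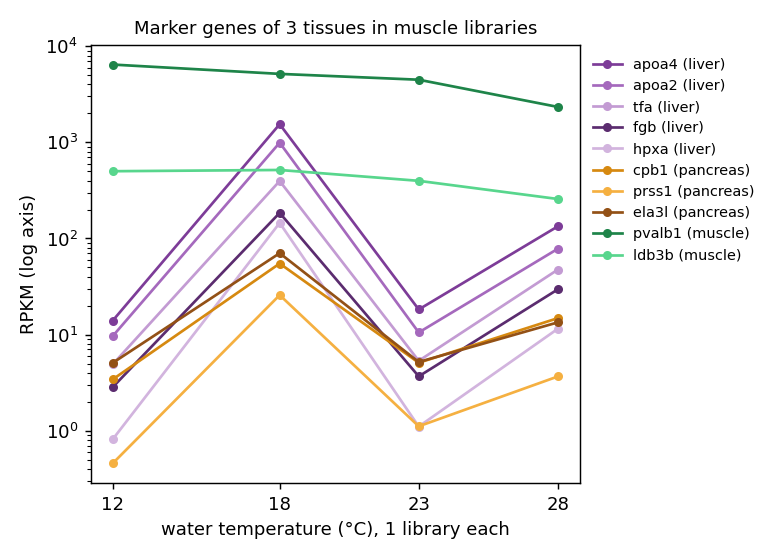
RPKM (log axis) of marker genes of liver (purple), exocrine pancreas (orange) and skeletal muscle (green) against water temperature (°C) in the muscle samples, with 1 library per point. The liver gene apoa4 is at 1544 RPKM at 18 °C and at 14, 18.3 and 133.6 RPKM in the other libraries, while the muscle gene ldb3b lies between 257.4 and 515.8 RPKM.

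Among genes with a symbol, a mean of at least 5 RPKM over the pair and values above 0, cxcl13, fbxo32, arg2 and slc7a5 had the largest negative folds at 18 °C. The muscle ubiquitin ligase gene fbxo32 was at 103.4, 16.2, 12.7 and 17.2 RPKM from 12 to 28 °C. The arginase gene arg2 was at 36.0, 7.72, 4.01 and 31.98 RPKM and the amino acid transporter gene slc7a5 at 18.3, 4.55, 2.48 and 1.495 RPKM. The chemokine gene cxcl13 was at 0.218 and 0.056 RPKM at 18 and 23 °C. At 23 °C the glutamine synthetase gene glula was also among the 5 genes named by the same rule, at 72.2, 20.3, 9.21 and 14.6 RPKM from 12 to 28 °C. The wider lists of muscle protein breakdown and glucocorticoid response did not stand apart at 18 °C, with medians of -0.17 and -0.19 at the 17.64 and 9.84 percentiles. The breakdown list had 0 members higher and 1 lower of 7, and the glucocorticoid list 2 higher and 1 lower of 12. The 2 higher genes, tat (0.0814 and 8.82 RPKM at 12 and 18 °C) and mt2 (46.9 and 339.9 RPKM), were in the same cluster of the authors' deposited table as the liver genes named above. At 23 °C their medians were -0.49 and -0.48, at the 4.79 and 2.51 percentiles, with 0 members higher and 3 lower of 7 and with 0 higher and 5 lower of 11. At 28 °C the breakdown list had 3 members higher and 4 lower of 8, and the glucocorticoid list 4 higher and 3 lower of 13. A value of exactly 0 in a table without counts can be a failed estimate. The myosin light chain gene mylpf was listed at 0 at 18 °C, against 25770 RPKM at 12 °C and 25860 RPKM at 23 °C. The calcium pump gene atp2a1l was likewise listed at 0 at 23 °C, against 15860 RPKM at 12 °C, and no fold is given for either, although each is 1 of the 110 and 408 genes counted as lower at its temperature.

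At 23 °C the genes furthest above 12 °C, among those with a symbol and a mean of at least 5 RPKM over the pair, were serpinh1b, hspa1b, acta1a, hsp90aa1.1 and nppcl2. The collagen chaperone gene serpinh1b was at 1.74, 7.73, 36.0 and 168.6 RPKM from 12 to 28 °C. The skeletal actin gene acta1a was at 66.9, 395.5, 417.1 and 308.9 RPKM, and the natriuretic peptide gene nppcl2 at 2.08, 2.16, 12.0 and 2.30 RPKM. Contractile genes had a median of 0.35 at 18 °C, above all 10000 random lists, with a mean of -0.08 that includes mylpf, and of 0.20 at 23 °C, at the 99.96 percentile.

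The temperature slope over the 4 libraries asked which genes changed steadily with warming. Among genes with a symbol and a maximum of at least 5 RPKM, those with the smallest unadjusted p are given here as values and not as calls. Of these, serpinh1b had a slope of 0.374 ± 0.034 (SE) log2 units per °C. The small GTPase gene arf4 (0.0677 to 22.5 RPKM from 12 to 28 °C), the cytochrome oxidase subunit gene cox6b1 (11.3 to 80.4 RPKM), calu (2.32 to 37.1 RPKM), egln2 (10.9 to 90.7 RPKM) and the creatine transporter gene slc6a8 (13.3 to 106.8 RPKM) were on the same side. So were p4ha2, selenom, fkbp7 and trnau1apb, with slopes of 0.296, 0.117, 0.132 and 0.117. On the negative side were lrtm1 (15.0 to 1.32 RPKM), the lipin gene lpin1a (6.40 to 0.442 RPKM), mast4 (12.2 to 0.829 RPKM), gpc6 (7.68 to 0.464 RPKM) and the sodium-calcium exchanger gene slc8a3 (6.78 to 0.588 RPKM). The muscle transcription cofactor vgll2b, ptpn21, sesn1, the splicing regulator mbnl1 and the pyruvate dehydrogenase kinase pdk2a had slopes of -0.172, -0.136, -0.174, -0.185 and -0.174. With limma and Benjamini-Hochberg adjustment, 0 of 4075 genes passed, the smallest adjusted p was 0.193, and 1038 genes had an unadjusted p under 0.05. A straight line treats part of a change confined to 28 °C as scatter. Of the 1497 genes higher at 28 °C, 1295 lay within 2-fold of 12 °C at both 18 and 23 °C. So did 711 of the 984 lower genes. Within 2-fold does not mean unchanged: 679 of the 984 lower genes were lower at each step from 12 to 28 °C. Of the 1497 higher genes, 393 were higher at each step. Only 1116 and 1077 of the higher genes also met the minimum at 18 and 23 °C. The others lay below it there, where folds of RPKM + 1 leave little room for a 2-fold difference. The count of 0 does not show that expression was unaffected by temperature. Of the 29 heat shock genes fitted, 28 had a positive slope and 1 a negative slope, none passed over all genes, and 1 passed when adjusted over the list alone.

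Tested as lists with camera at the preset correlation, 5 of 23 lists had higher slopes than the other genes. They were heat shock (adjusted p = 1.04e-08), endoplasmic reticulum stress (2.18e-08, 23 of 23 slopes positive), immediate early genes (7.1e-05, 16 of 17), glycolysis (0.0172, 9 of 10) and apoptosis and p53 (0.0352, 10 of 11). With an estimated correlation none of the 5 calls held (adjusted p = 0.909 with an estimated correlation for each). By fry the smallest adjusted p over the 23 lists was 0.121, for the circadian clock and cholesterol synthesis lists. For the circadian clock, 11 of 14 slopes were negative, and 4 genes passed when adjusted over the list alone. The liver markers had 25 of 28 positive slopes and an adjusted p of 0.325 at the preset correlation.

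In the authors' deposited table, 2383 genes were at least 2-fold higher and 1833 lower at 18 °C, 2558 and 1981 at 23 °C, and 4733 and 4201 at 28 °C. These numbers use the authors' constants and no minimum expression. Of the 2-fold calls in the authors' deposited table, 80.8%, 79.5% and 57.0% at 18, 23 and 28 °C had a mean below 1 RPKM over the pair.

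Markers of other cell types were checked in each library. Gill epithelium markers had a mean log2(RPKM + 1) between 0.31 and 0.49, and erythroid markers between 0.12 and 0.36, in the 4 libraries. Leukocyte markers were at 1.38, 0.86, 0.75 and 1.95 from 12 to 28 °C, with list medians of -0.40 and -0.55 on the log2 scale at 18 and 23 °C (percentiles 0.07 and 0.36) and 0.55 at 28 °C. The B cell gene cd79a was at 2.28, 0.199, 0.077 and 6.21 RPKM. The gill and erythroid lists have 9 and 6 rows here, against 19 and 13 matches among the RefSeq genes. In each comparison 1 gill marker and 0 erythroid markers met the minimum. Markers at a steady level are left out by the selection, so the low means do not show that such cells were absent.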

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

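Scaling by the authors' constants and leaving out the liver, pancreas and acute phase lists were chosen after seeing the data. With a pseudocount of 0.1 the count of genes at least 2-fold apart from 12 °C was 685 at 18 °C (424 with 1) and 964 at 23 °C (521 with 1), and the median log2 fold of the liver list at 18 °C was 5.82 (4.67 with 1), since a smaller pseudocount widens the folds of low genes. The counts without a filter, with either scaling and without the 3 lists were within 1.5 times the main counts, and so was the count at 28 °C with a pseudocount of 0.1 (3464 against 2481). The 10 genes named at 28 °C kept their direction and at least a 2-fold difference in all 30 values under the pseudocount and the 2 scalings. They were chosen for the largest folds, which these settings are too small to undo, so this outcome was fixed in advance. The heat shock median at 28 °C ranged from 3.30 to 3.70. For the temperature slope, 0 genes passed limma's adjusted threshold with either pseudocount, without a filter, with either scaling and in each fit that left out 1 library; unadjusted p under 0.05 was reached by 395 to 1142 genes in those 4 fits. The slope without the 18 °C library, the one with the liver markers, gave 0 calls and 395 genes at an unadjusted p under 0.05. Camera called 5 of 23 lists as deposited, 0 with an estimated correlation, 4 with median scaling and 6 with the authors' constants, and which lists were shared between these settings was not counted. The estimated correlation is taken from the scatter of list members about the fitted line, on 2 residual degrees of freedom. It was 0.752, 0.917 and 0.943 for the heat shock, endoplasmic reticulum stress and immediate early lists. Curvature that list members share, such as a common rise from 23 to 28 °C, counts towards it. How much of the correlation is such curvature was not tested. No fit against 28 °C as a factor, in series A, over both series or over all 24 samples was run, because the table used here has 4 columns of 1 series. No paired analysis was possible because each temperature has 1 library. The fold counts have no replicate error, and the absolute depth behind them is unknown.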

Other observations

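All tests of explanations below were chosen after the results they concern had been seen. Members of further lists are named here after their values were seen. The autophagy receptor sqstm1 was at 16.02 RPKM at 12 °C and 137.6 RPKM at 28 °C, the polyubiquitin gene ubb at 317.0 and 1405 RPKM, and the survival gene mcl1b at 686.9 and 1655 RPKM. The sliding-clamp gene pcna was at 6.87 and 43.8 RPKM, although the other cell cycle genes that met the minimum, rrm2b and mcm7, were at 10.01 and 3.10 RPKM at 12 °C and at 3.21 and 1.55 RPKM at 28 °C. The carnitine transferase gene cpt1b was at 14 and 2.90 RPKM and fdft1 of sterol synthesis at 8.72 and 1.69 RPKM. The antimicrobial peptide gene leap2 was at 1.56, 17.7, 4.65 and 58.7 RPKM from 12 to 28 °C and so, unlike the other acute phase genes named, was higher at 28 than at 18 °C. Of the rows without a symbol, LOC109626154 was at 0.0251 RPKM at 12 °C and 2264 RPKM at 28 °C, and LOC109626317 at 0.0681 and 2121 RPKM.

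The liver and pancreas markers were high in the 18 °C library and, less so, in the 28 °C library. Liver RNA carried into these libraries is a candidate explanation. Over 34 liver genes, the log2 ratio of the 28 to the 18 °C value had an interquartile range of 0.46. This lay below the 1.22 to 3.64 of random lists, so the genes kept nearly the same ratio. The acute phase and complement list, also high at 18 °C, did not keep 1 ratio. Over its 23 genes used the interquartile range was 1.83, inside the 1.27 to 3.72 of its random lists. A material of fixed liver and pancreas makeup in both libraries is argued against but not excluded. The excess at 28 °C was a median share of 0.099 of that at 18 °C for liver genes (quartiles 0.082 and 0.114). For pancreas genes it was 0.191 (0.14 and 0.211). These quartiles do not overlap, but they rest on 7 pancreas genes and on the 12 °C library as the only baseline. A response of muscle to 18 °C stays open, since there is 1 column per temperature. The liver median of 0.024 at 23 °C decides nothing about it. Of the liver and pancreas markers, 14 of 38 and 4 of 7 were also at 1 RPKM or more in the 12 °C library, and reads from the liver samples of the series were not analysed here.

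For most of the authors' 2-fold calls on rows that could be read as whole reads, counting error and a real difference cannot be told apart. Calls on other low genes were not tested. Among rows that could be read as whole reads, 76.8% of 1239 calls at 18 °C, 84.4% of 1285 at 23 °C and 65.5% of 1537 at 28 °C had an exact binomial p of 0.05 or more. Only 6.5%, 3.0% and 7.0% of these calls had enough reads for a difference of exactly 2-fold to reach a p under 0.05, so a real difference near 2-fold would mostly go unseen. The test had a p under 0.05 for 287, 201 and 531 of the calls at 18, 23 and 28 °C. The readings are the smallest possible, which raises p, and the shares do not extend to genes above 1 RPKM, of which 17 could be read. Temperature as a cause of these calls was not tested.

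The genes fbxo32, glula, arg2, cxcl13 and slc7a5 were lower at 18 and 23 °C than at 12 °C. The median log2 fold of the 5 genes was -1.97 or lower at both temperatures under each scaling. The offsets removed by median ratio scaling were -0.112 and -0.33 log2 units at 18 and 23 °C, and the authors' constants correspond to -0.087 and 0.347. Scalings of this size could not remove folds picked for being large, so this outcome was fixed in advance. It shows only that the scalings used are too small to account for these folds. For fbxo32, a 12 °C library that stands apart and a response complete at 18 °C cannot be told apart, because both predict genes that are lower in all 3 warmer libraries, of which there were 56, and the table has 1 column for 12 °C. Neither alone covers arg2, which was at 36.0 RPKM at 12 °C and 31.98 RPKM at 28 °C, or slc7a5, which was at 4.55 RPKM at 18 °C and 1.495 RPKM at 28 °C. The values of glula were 20.3, 9.21 and 14.6 RPKM at 18, 23 and 28 °C. Leukocyte markers were also lower at 18 and 23 °C, with a mean log2(RPKM + 1) of 1.38, 0.86, 0.75 and 1.95 from 12 to 28 °C, and whether the chemokine gene cxcl13, at 1.69 RPKM at 28 °C, goes with them was not tested.

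For the slope count of 0, the 12 distinct orders of the 4 libraries along the temperature axis decide nothing: every order must give at least 0 genes, and 12 orders are too few for a share below 0.05. The highest count passing after adjustment among the other orders was 186, and what drives it was not tested. By limma's unadjusted p under 0.05, the temperature order had the most genes of the 12 orders, 1038. The other orders had 20 to 639, and the order with 186 had 639. With 12 orders this ranking cannot reach a share below 0.05 either.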
